A study of Mus musculus with 2 samples.

How the data were processed

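The data were 2 droplet (10x Chromium) single-cell RNA libraries of mouse leptomeninges, R1 and R2, which the labels put in 1 group. Per the labels, the tissue was peeled from cerebral hemispheres of male and female Pdgfra-H2BGFP mice aged 3 months, digested to single cells and loaded for at most 5000 recovered cells per sample. The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 (per the file headers) against genome build mm10. The matrices hold whole numbers over 32287 features, and every barcode has at least 500 UMIs. The deposited feature and barcode lists give a gene symbol beside its Ensembl identifier, and a cell barcode (unit: other, per the file headers), in the order of the matrix. GFP and tdTomato are listed as features. The libraries shared 93 barcode sequences.

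Cells were kept with at least 400 genes and at most 10% mitochondrial UMIs, and Scrublet was run per library at an expected doublet rate of 0.05. It called 4 of 2988 barcodes of R1 (0.134%) and 1 of 3038 of R2 (0.0329%), far below that rate, so doublet removal did almost nothing here and doublets are likely to remain among the cells. The true rate was not measured. In R1, 1314 barcodes were under the gene limit and 2974 over the mitochondrial limit, and in R2 1369 and 2336. The kept cells held 7622094 and 6276148 UMIs.

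Counts were log-normalized and clustered in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 with igraph 0.11.9). The genes of the functional lists, Pdgfra, the sex-linked genes and the reporters were left out of the variable genes. Fibroblast-like clusters were clustered again among themselves at resolution 0.8. Clusters were named by the highest score among 25 marker lists, except the list of dividing cells, which gave no name. A score was the mean log2 level of a list's genes in the cluster minus their mean over clusters. In the second round the name came only from the pial and perivascular, inner arachnoid, arachnoid barrier and dural border lists. Scores there were relative to the fibroblast-like clusters alone. Clusters took a number where no class stood out, where another cell class or several scored as high, or where more markers of another class than of their own were among the 10 leading genes. Some numbers were given because a cluster held no own marker among these, but a clear score without one was enough for a name. The other tools were python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

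Shares of cells are given per library with exact (Clopper-Pearson) 95% binomial intervals. Intervals and floors cover counting error only, and a count of 0 allows 3 counts. For the share of cells with a Pdgfra UMI, cells were thinned to 1000 UMIs and shallower cells left out.

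Raw counts were summed per library and class for classes with at least 50 cells in each library. edgeR's quasi-likelihood test (TMM normalization, filterByExpr, library as a block) was used with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. The first fit held 8 named classes and left 7 residual degrees of freedom, with a biological coefficient of variation of 0.116. It gave fibroblast-like against other classes and arachnoid barrier-like against endothelial-like cells. The second fit held the 5 fibroblast-like classes, cluster F06 included by its number, and left 4 residual degrees of freedom (0.110). It gave each class against the mean of the others. The printed standard error is the size of the log2 fold change over the square root of its F statistic. Fold changes are differences of mean logs, so that a class with a very high level can raise the mean CPM of its side above what the fold change shows. Differences in log CPM between R1 and R2 were also taken per class for the more abundant genes. Across genes they correlated only weakly between classes. The median correlation was 0.137 over 28 pairs of classes in the first fit and 0.133 over 10 pairs in the second.

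The 15 functional lists, the marker lists and the rule for named genes were fixed before the data were examined. The cutoffs of the rule that named the clusters were chosen after the clusters had been seen. Named genes were Pdgfra and, per list and comparison, up to 2 members (fibroblast-like classes) or up to 3 (the other comparisons) with the largest fold change that passed in both libraries' direction with at least 50 CPM on the higher side, and some genes that this rule names are not reported here. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 105 tests of lists and comparisons, and again with the correlation estimated. Of these, 37 passed with the preset and 0 with the estimated correlation, where 27 had an unadjusted p below 0.05 and the lowest adjusted p was 0.0692. Fold changes against 0 counts are lower bounds against a floor of 3 counts, and those against 1 to 3 counts are ratios of pooled CPM with a counting interval.

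The test was tried on simulated data with changes of 1.5-, 2- and 4-fold put into about 67 genes each, all above a low level of expression. Counts were simulated independently for fixed classes, whereas the real classes were drawn from the same counts that were tested. The simulated shares of false calls therefore do not give the error of the real calls. For fibroblast-like against other classes 43.3%, 82.1% and 97.0% of them were recovered and 5.13% of all calls were false. For arachnoid barrier-like against endothelial-like cells the recovered shares were 5.97%, 28.4% and 84.9%, with 3.66% false calls. Among the fibroblast-like comparisons the share recovered at 2-fold ranged from 35.8% (arachnoid barrier-like) to 76.1% (dural border-like), and the share of false calls from 3.33% to 7.44%.

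The alternatives set in advance were a lower (0.6 and 0.5) and a higher (1.4 and 1.2) resolution, list genes kept in the clustering, at least 1000 genes, at most 5% mitochondrial UMIs, no doublet removal, no library block, DESeq2's size factors, DESeq2's Wald test, no filter on low counts, at least 20 cells, count splitting (classes drawn on a random part of each cell's UMIs and tested on the rest), equal UMI totals, cells thinned to 2000 UMIs, the estimated correlation and leaving out each library. Added after seeing the data were at most 25% mitochondrial UMIs, removal of the top 5% of doublet scores, barcodes with at least 1% Malat1 UMIs, leaving out cluster F06, Pdgfra of each class against the named classes that are not fibroblast-like and the dissociation response against each other class alone. No scaling alternative moved the share of called genes that were higher by more than 10 points.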

Results

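Single-cell RNA was measured in 2 libraries, R1 and R2, of leptomeninges peeled from the cerebral hemispheres of adult mice aged 3 months. The mice carried Pdgfra-H2BGFP, a reporter that puts a nuclear fluorescent protein under the control of Pdgfra, and the labels name males and females. The libraries formed 1 group, so every comparison below is between cell classes within the libraries (n = 2). R1 held 7276 barcodes with 14586462 UMIs (unique molecular identifiers, 1 per captured transcript) and R2 held 6743 barcodes with 12359040 UMIs. The medians were 1172.5 and 1024 UMIs per barcode. After filtering, 2984 cells of R1 and 3037 cells of R2 remained, with medians of 1642.5 and 1249 UMIs and of 907 and 721 genes. The labels do not say whether the libraries came from separate animals. With library as a block, the p-values measure only how the differences between classes varied between these libraries.

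Fibroblast-like cells made up 46.95% of the kept cells of R1 (exact 95% binomial interval 45.1 to 48.8) and 51.1% of those of R2 (49.3 to 52.9), a mean of 49.0% ± 2.96 (SD, n = 2). Scores of marker genes named 4 fibroblast-like classes in them. Dural border-like cells, in clusters led by genes such as Kcne4 and Slc47a2, were 16.5% of R1 (15.2 to 17.9) and 9.78% of R2 (8.75 to 10.9). Inner arachnoid fibroblast-like cells, led by Ppp1r1a, were 7.94% (6.997 to 8.97) and 13.6% (12.4 to 14.9). Pial and perivascular fibroblast-like cells, led by Lamc3, were 6.37% (5.52 to 7.30) and 4.08% (3.41 to 4.85). Arachnoid barrier-like cells, led by Dpp4 and Cldn11, were 4.06% (3.38 to 4.83) and 2.21% (1.71 to 2.79). The names of both dural border-like clusters, F00 and F03, and of the inner arachnoid cluster F07 rest on marker scores alone (1.01, 0.92 and 1.32 on the log2 scale), with 0 markers of the class among their 10 leading genes. The leading genes of F00 included the antigen presentation genes Cd74 and H2-Ab1, and those of the inner arachnoid cluster F02 the immunoglobulin genes Igha and Igkc, none of which is a marker gene here. Each of these 4 shares differed between the libraries by more than its counting interval. The next fibroblast-like cluster, F06, was 9.85% of R1 (8.81 to 10.98) and 19.6% of R2 (18.2 to 21.0) and took no layer name, since erythroid markers scored above those of the layers (0.97 against at most 0.25) and the astrocyte marker Aqp4 was among its leading genes. The smaller clusters F01, led by the neuronal gene Camk2a, and F08, led by the macrophage gene C1qa, made up 0.967% and 1.08% of the cells on average.

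Outside the fibroblasts, border macrophage-like cells were the largest class, with 17.6% of R1 (16.2 to 19.0) and 22.0% of R2 (20.5 to 23.5). Endothelial-like cells made up 10.8% and 10.4%, microglia-like cells 6.40% and 3.39%, and mural-like cells, which are pericytes and smooth muscle cells, 1.68% and 1.78%. Erythroid-like, T or NK-like, B-like and neutrophil-like cells averaged 1.96%, 1.43%, 0.416% and 0.332%. The unnamed cluster C05 held neuronal transcripts such as Nrgn and made up 8.14% of R1 and 2.60% of R2. The unnamed clusters C10, led by Meg3, and C19, led by Ighg2b, averaged 1.44% and 2.99%. The shares depended on the filters: with at most 5% mitochondrial UMIs the fibroblast-like share was 34.5%, and with at least 1000 genes per cell the arachnoid barrier-like share was 1.09%.

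**Figure D1:**
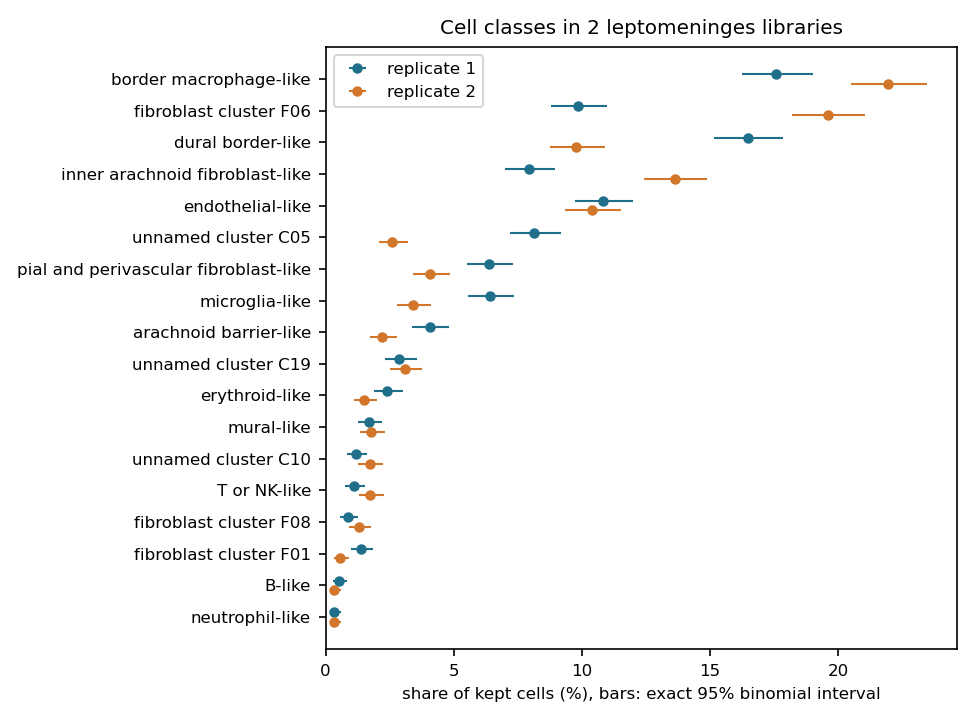
Share of kept cells in percent (horizontal axis) for each cell class or unnamed cluster (vertical axis), with 1 point per library and bars for the exact 95% binomial interval. Border macrophage-like cells reached 17.6% and 22.0%. The intervals of the 2 libraries lay apart for the dural border-like, inner arachnoid fibroblast-like, pial and arachnoid barrier-like classes. They also lay apart for border macrophage-like and microglia-like cells and for clusters F06, F01 and C05.

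Classes also differed in the nuclear RNA Malat1, a sign of how much nuclear RNA a barcode holds. At least 1% of UMIs were Malat1 in 95.1% and 89.6% of dural border-like cells, 91.6% and 90.3% of pial cells, 90.9% and 83.6% of arachnoid barrier-like cells, and 87.6% and 81.0% of endothelial-like cells. The share was 31.6% and 19.1% of inner arachnoid fibroblast-like cells, 28.0% and 24.7% of border macrophage-like cells, and 6.12% and 4.03% of cluster F06. The inner arachnoid fibroblast-like class joined cluster F02, with 162 and 340 cells of which 3.09% and 2.65% reached 1% Malat1, and cluster F07, with 75 and 74 cells of which 93.3% and 94.6% did. Border macrophage-like cells likewise joined cluster C04, with 161 and 181 cells, and cluster C07, with 364 and 486. In C04 88.8% and 87.3% of cells reached 1% Malat1, and in C07 1.10% and 1.44%. Microglia-like cells joined cluster C11, where 93.1% and 93.0% did, and cluster C08, where 1.92% and 1.67% did. Cluster F06 also had the lowest median depth of the fibroblast-like classes, 740.5 and 776 UMIs, and a median of 8.03% and 7.83% mitochondrial UMIs.

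**Figure D2:**
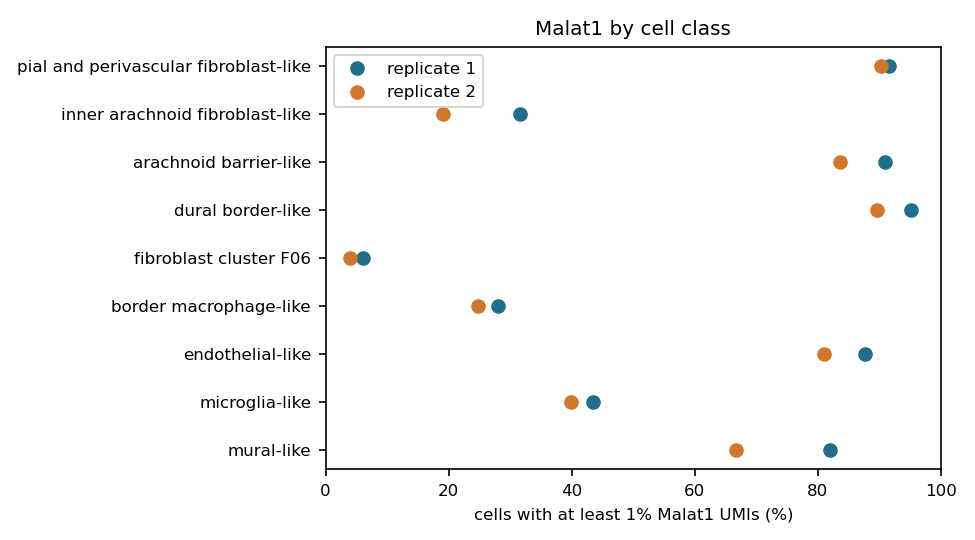
Percent of cells in which at least 1% of UMIs were Malat1 (horizontal axis) by class (vertical axis), with 1 point per library. Dural border-like cells reached 95.1% and 89.6%, inner arachnoid fibroblast-like cells 31.6% and 19.1%, and cluster F06 6.12% and 4.03%.

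The first comparison asked what sets the fibroblast-like cells of the leptomeninges apart from the endothelial-like, mural-like, border macrophage-like and microglia-like cells of the same suspension. Its fibroblast-like side was the mean of the named fibroblast-like classes with equal weight. Cluster F06, with 889 cells, and the smaller clusters F01 and F08 were not part of it. Fold changes are differences of mean log2 levels with their standard error, and CPM values, counts scaled to a common total of UMIs, are means over the classes of a side in R1 and R2. The gap junction gene Gja1 was higher by 3.64 ± 0.14 on the log2 scale (939.3 and 740.0 CPM against 65.1 and 45.8), and Gjb2 and Gjb6 were higher by 3.48 ± 0.14 and 3.44 ± 0.13. The potassium channel gene Kcnj13 was higher by 4.57 ± 0.39 and the monocarboxylate transporter gene Slc16a11 by 3.95 ± 0.14. The immediate-early genes Fos and Fosb, which cells switch on under stress, were lower, with log2 fold changes of −5.70 ± 0.17 and −6.92 ± 0.39. Fos stood at 23.0 and 1.90 CPM in fibroblast-like cells and at 967.3 and 1121 CPM in the other classes.

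Collagen genes were higher as a group in fibroblast-like cells. Of 19 tested members 16 were higher and 0 lower (17 and 0 adjusted over the list alone), with Col11a1 at +4.33 ± 0.45 and Col25a1 at +3.78 ± 0.22. The list's adjusted p was 6.0e-09, and the adjusted p = 0.117 with an estimated correlation. Of 22 proteoglycan and matrix glycoprotein genes 18 were higher and 1 lower (18 and 2 adjusted over the list alone), among them Omd at +3.25 ± 0.27 (list adjusted p = 6.3e-08; adjusted p = 0.117 with an estimated correlation). Of 14 basement membrane genes 8 were higher and 2 lower (9 and 2 over the list alone), with Lama2 at +2.86 ± 0.17 (list adjusted p = 0.00256; adjusted p = 0.273 with an estimated correlation). Transcription factors of the meninges gave 22 higher and 1 lower of 25, the same counts over the list alone, with Zic4 at +3.70 ± 0.15 and Foxd1 at +3.40 ± 0.14 (list adjusted p = 1.7e-13; adjusted p = 0.117 with an estimated correlation). BMP and WNT pathway genes gave 14 higher and 1 lower of 16 (15 and 1 over the list alone), with the BMP ligands Bmp5 at +3.64 ± 0.20 and Bmp4 at +3.32 ± 0.15 (list adjusted p = 6.3e-08; adjusted p = 0.118 with an estimated correlation).

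Transporter genes were higher on balance. Of 36 carriers of organic ions and nutrients 26 were higher and 6 lower, with the organic anion carrier Slco2b1 at −4.29 ± 0.94 (list adjusted p = 4.3e-06; adjusted p = 0.117 with an estimated correlation). Of 22 inorganic ion and water transport genes 12 were higher and 5 lower, with the bicarbonate carrier Slc4a10 at +2.92 ± 0.13 (list adjusted p = 0.00256; adjusted p = 0.120 with an estimated correlation). Of 15 ABC transporter genes 8 were higher and 1 lower, with Abca2 at +1.85 ± 0.20 (list adjusted p = 0.0139; adjusted p = 0.120 with an estimated correlation), and this list did not pass with classes drawn and tested on separate random parts of the counts (adjusted p = 0.0820). All 3 transporter lists gave the same counts adjusted over the list alone. Genes of adherens junctions, desmosomes and gap junctions gave 7 higher and 1 lower of 19, again the same over the list alone (list adjusted p = 0.0130; adjusted p = 0.162 with an estimated correlation). Growth factor and IGF pathway genes gave 12 higher and 4 lower of 22 (13 and 4 over the list alone), with Vegfa at +2.86 ± 0.31 and Igfbp6 at +2.85 ± 0.12 (list adjusted p = 0.00256; adjusted p = 0.258 with an estimated correlation).

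The dissociation-response genes gave 0 higher and 17 lower of 17, over all genes and adjusted over the list alone, with Junb at −4.87 ± 0.14 (list adjusted p = 1.4e-13; adjusted p = 0.120 with an estimated correlation). Against each other class alone, a comparison added after seeing the data, 17 of these 17 genes were lower than in endothelial-like cells, 15 than in mural-like, 14 than in microglia-like and 7 than in border macrophage-like cells. Among barcodes with at least 1% Malat1 UMIs, likewise added after seeing the data, 15 of 17 were lower. Of the lists whose test did not pass, tight junction genes gave 7 higher and 3 lower of 11 (adjusted p = 0.227) and retinoid pathway genes 5 higher and 1 lower of 9 (adjusted p = 0.108). Genes of cytokines, chemokines and complement gave 6 higher and 2 lower of 16 (adjusted p = 0.376), and prostaglandin and lipid carrier genes 7 higher and 5 lower of 14 (adjusted p = 0.102). In both of these last lists the median and the mean of the log2 fold changes had opposite signs.

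Over all genes, 5095 of 10564 passed, 2819 higher and 2276 lower in fibroblast-like cells. Of the 11 lists that passed with the preset correlation, 0 passed with an estimated one. The ABC transporter gene Abcc4, at +1.59 ± 0.27, turned to −0.35 with at most 5% mitochondrial UMIs, where 5 rather than 8 classes were left in the fit, and was 0.90 without R2. Values of a single library, here and in the comparisons below, were taken from logs with a prior count of 2. They were smaller for genes with few counts on a side: Col11a1 had 2.82 and 3.07 and Fosb −4.38 and −4.55. A gap between such a value and the fitted one need not come from leaving out a library.

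Pdgfra, the gene that drives the reporter of these mice, was followed across classes. It encodes the platelet-derived growth factor receptor alpha (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215 on the plus strand of mm10, where the annotation also places Mir7025). Pial and perivascular fibroblast-like cells had 246 and 192 CPM, a mean of 219 ± 38.5 (SD, n = 2), and inner arachnoid fibroblast-like cells 72.5 and 65.1 CPM (68.8 ± 5.23). Arachnoid barrier-like cells had 15.8 and 37.3 CPM (26.5 ± 15.2), dural border-like cells 16.9 and 23.8 CPM (20.3 ± 4.89) and cluster F06 15.1 and 12.5 CPM. Border macrophage-like cells had 10.2 and 11.9 CPM, endothelial-like cells 6.71 and 3.34, and microglia-like cells 3.48 and 0. The unnamed cluster C10 had 52.4 and 129 CPM, on 5 and 18 UMIs and with a mean of 90.7 above that of inner arachnoid cells, and the unnamed cluster C05 had 56.7 and 15.5 CPM, on 39 and 3 UMIs. In mural-like cells 0 counts were seen, which allows up to 37.6 and 42.1 CPM.

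With every cell thinned to 1000 UMIs, a Pdgfra UMI was seen in 24.8% of pial cells of R1 (18.3 to 32.4) and 20% of R2 (11.9 to 30.4), and in 9.09% (4.93 to 15.04) and 9.27% (6.03 to 13.5) of inner arachnoid fibroblast-like cells. The background in border macrophage-like cells was 1.07% (0.291 to 2.71) and 0.973% (0.266 to 2.47). Median depths before thinning were 2076.5 and 1489 UMIs in pial cells and 1453 and 1213 in border macrophage-like cells. Dural border-like cells had 1.88% (0.814 to 3.67) and 2.06% (0.671 to 4.74), and arachnoid barrier-like cells 0% of 102 cells and 3.64% of 55 (0.443 to 12.5). Both classes overlapped the background, so expression in single cells was not detectable there at this depth.

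The named fibroblast-like classes together, without clusters F06, F01 and F08, had higher Pdgfra than the other classes, by 4.24 ± 0.47 on the log2 scale (87.8 and 79.4 against 5.09 and 3.82 CPM, adjusted p = 6.4e-18, higher in both libraries, with single-library values of 2.62 and 3.25). The mean CPM of their side rested mostly on pial cells, with 246 and 192 CPM. Against the other fibroblast-like classes, pial cells were higher by 3.09 ± 0.22 (adjusted p = 1.3e-18) and inner arachnoid fibroblast-like cells by 1.4 ± 0.26 (adjusted p = 2.4e-05). Dural border-like cells were lower, at −1.45 ± 0.31 (adjusted p = 1.5e-04), as was cluster F06, at −1.89 ± 0.41 (adjusted p = 1.2e-04). Arachnoid barrier-like cells had −1.15 ± 0.43, which did not pass (adjusted p = 0.072) and passed without cluster F06, at −1.76. With cluster F06 included, the value was −0.47 without R1 and −1.56 without R2. The call for inner arachnoid fibroblast-like cells was lost with at most 5% mitochondrial UMIs (0.15) and with classes drawn and tested on separate random parts of the counts (0.29), and that for dural border-like cells was lost with equal UMI totals (−0.66). In the first 2 of these settings pial and dural border-like cells alone formed the other side, without the arachnoid barrier-like cells and cluster F06, so the change of setting and of comparison group cannot be separated. Against the mean of the endothelial-like, mural-like, border macrophage-like and microglia-like classes, a test added after seeing the data, all 4 named fibroblast-like classes were higher, from +2.74 ± 0.72 in dural border-like cells to +6.30 ± 0.37 in pial cells. In that mean, mural-like cells had 0 counts and microglia-like cells 2 and 0. The size of these fold changes, and of the 4.24 above, therefore rests partly on classes near 0 counts. Border macrophage-like cells alone had 10.2 and 11.9 CPM, against 16.9 and 23.8 in dural border-like cells. No UMI of GFP or tdTomato, both listed among the features, was seen in either library, which by counting error alone allows up to 0.206 and 0.243 CPM. The sequences used for these features are not given, so it is unknown whether reads of the reporter could map to them. The 0 counts therefore do not show that the reporter was not transcribed.

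**Figure D3:**
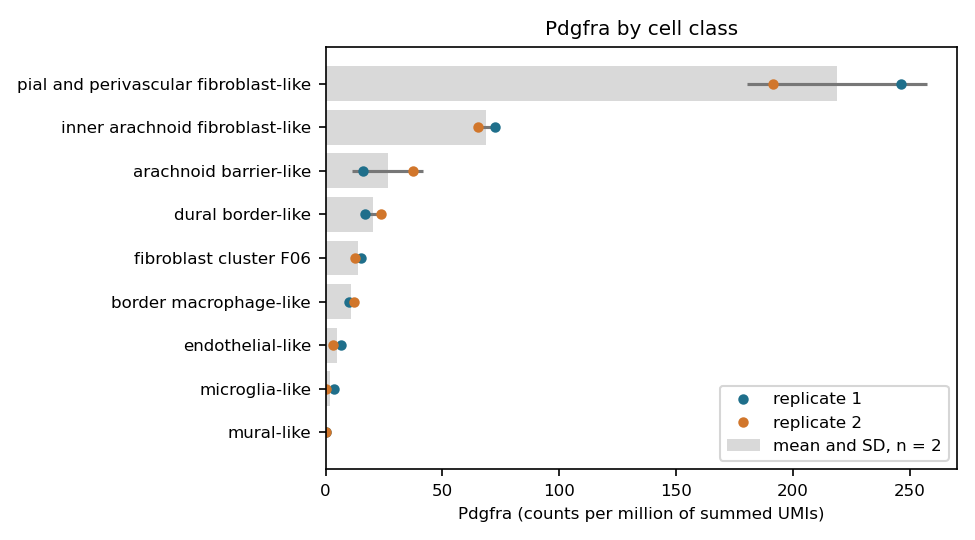
Pdgfra in CPM of summed UMIs (horizontal axis) by class (vertical axis), with 1 point per library and bars and lines for the mean and SD (n = 2). Pial and perivascular fibroblast-like cells had 246 and 192 CPM and inner arachnoid fibroblast-like cells 72.5 and 65.1, while every other class drawn stayed at or under 37.3.

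Each fibroblast-like class was then compared with the mean of the other fibroblast-like classes, cluster F06 included, to ask how the cells of the layers differ. Genes of the functional lists had been left out of the variable genes used for clustering, but genes that vary with them were not. Slc7a11 and Lum were among the leading genes of the pial cluster, Igfbp3 of the arachnoid barrier-like cluster, and Gdf10 and Thbs1 of 1 dural border-like cluster.

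Among the named genes higher in pial and perivascular fibroblast-like cells were transporter, matrix and ligand genes. Slc7a11, the cystine and glutamate exchanger (chromosome 3, 49892526 to 50443614), stood at 5196 and 4315 CPM against 224 and 234, a log2 fold change of +4.93 ± 0.16 (adjusted p = 9.6e-35). The nucleoside transporter gene Slc29a1 was higher by 5.44 ± 0.35 and the manganese exporter gene Slc30a10 by 4.98 ± 0.32. The ligand genes Bmp2 and Wnt4 were higher by 5.66 ± 0.39 and 4.08 ± 0.17. The efflux pump genes Abcb1a and Abcg2 were lower, at −2.35 ± 0.23 and −1.59 ± 0.21, the latter at −1.03 without R1.

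Of 34 organic ion and nutrient carriers 20 were higher and 8 lower in pial cells, over all genes and adjusted over the list alone (list adjusted p = 1.0e-14; adjusted p = 0.120 with an estimated correlation). Basement membrane genes gave 8 higher and 1 lower of 12 (9 and 1 over the list alone), with the laminin gene Lamb1 at +4.75 ± 0.31 (list adjusted p = 1.3e-06; adjusted p = 0.200 with an estimated correlation). Proteoglycan and matrix glycoprotein genes gave 11 higher and 3 lower of 20 over all genes and over the list alone, with Lum, which encodes lumican, at +4.57 ± 0.22 (list adjusted p = 3.6e-04; adjusted p = 0.273 with an estimated correlation). Of 9 cytokine, chemokine and complement genes 7 were higher and 1 lower over all genes and over the list alone, with the complement genes C4b at +3.15 ± 0.20 and C2 at +3.02 ± 0.28 (list adjusted p = 6.3e-08; adjusted p = 0.129 with an estimated correlation). BMP and WNT pathway genes gave 9 higher and 5 lower of 16 over all genes and over the list alone (list adjusted p = 2.2e-04; adjusted p = 0.162 with an estimated correlation). Growth factor and IGF pathway genes gave 9 higher and 6 lower of 22 (9 and 7 over the list alone), with Igfbp2 at +3.29 ± 0.14 (list adjusted p = 0.00157; adjusted p = 0.216 with an estimated correlation). That list's median log2 fold change, −0.38, and its mean, 0.33, had opposite signs.

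Prostaglandin and lipid carrier genes gave 4 higher and 2 lower of 9 in pial cells (4 and 3 over the list alone), with Apod, which encodes a lipid-binding apolipoprotein, at +2.39 ± 0.13 (list adjusted p = 0.0157; adjusted p = 0.273 with an estimated correlation). The dissociation-response genes gave 1 higher and 9 lower of 13 over all genes and over the list alone (list adjusted p = 0.0223; adjusted p = 0.577 with an estimated correlation). Among barcodes with at least 1% Malat1 UMIs, a choice made after seeing the data, 1 was higher and 3 lower of 11, and the list did not pass with classes drawn and tested on separate random parts of the counts (adjusted p = 0.234). Col13a1, which encodes a transmembrane collagen, was higher by 4.24 ± 0.28, and the gap junction gene Gjb2 by 2.09 ± 0.14. In all, 2559 of 8687 genes passed, 1409 higher and 1150 lower. The count was 750 with at most 5% mitochondrial UMIs, 3895 with at most 25%, 1106 among the barcodes rich in Malat1 and 1513 without cluster F06.

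Solute carrier and prostaglandin-related genes were among the named genes higher in inner arachnoid fibroblast-like cells. Slc6a20a, a proline transporter gene, reached 1510 and 837 CPM against 393 and 387, a log2 fold change of +3.56 ± 0.18 (adjusted p = 2.2e-25), and stood at 1447 and 1285 CPM in pial cells. The betaine and GABA transporter gene Slc6a12 was higher by 3.76 ± 0.26. Kcnj13 and Ptgfr, which encodes the prostaglandin F receptor, were both higher by 3.05, with standard errors of 0.19 and 0.24. Fmod, which encodes fibromodulin, was higher by 3.02 ± 0.15 (1122 and 889 CPM, with 1180 and 766 in pial cells), Spp1, which encodes osteopontin, by 2.94 ± 0.13, and the complement gene C2 by 3.66 ± 0.25.

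Of 34 organic ion and nutrient carriers 18 were higher and 8 lower in these cells (20 and 8 adjusted over the list alone; list adjusted p = 2.5e-11; adjusted p = 0.129 with an estimated correlation). That list did not pass with classes drawn and tested on separate random parts of the counts (adjusted p = 0.0971). Prostaglandin and lipid carrier genes gave 5 higher and 2 lower of 9 over all genes and over the list alone, with Enpp2, which encodes autotaxin, at +2.91 ± 0.17 (list adjusted p = 2.1e-09; adjusted p = 0.117 with an estimated correlation). Collagen genes were lower on balance, with 4 higher and 12 lower of 19 (4 and 14 over the list alone; list adjusted p = 4.4e-05; adjusted p = 0.117 with an estimated correlation). ABC transporter genes gave 1 higher and 6 lower of 11 (1 and 7 over the list alone), with Abcb1a at −1.52 ± 0.20 and Abcc4 at −1.82 ± 0.30, or −2.78 without R2 (list adjusted p = 0.00263; adjusted p = 0.120 with an estimated correlation). Proteoglycan and matrix glycoprotein genes gave 5 higher and 7 lower of 20 (7 and 9 over the list alone), and their test did not pass (adjusted p = 0.151), with a median log2 fold change of −0.38 and a mean of 0.18. Among barcodes with at least 1% Malat1 UMIs, whose inner arachnoid cells lay mostly in cluster F07, 17 carriers were higher and 8 lower of 31, 5 prostaglandin and lipid carrier genes higher and 3 lower of 8, 4 collagen genes higher and 11 lower of 18, and 1 ABC transporter gene higher and 3 lower of 10.

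In all, 1696 of 8687 genes passed, 1043 higher and 653 lower. The count was 2804 at the lower cluster resolution, 735 with at most 5% mitochondrial UMIs and 1042 among the barcodes rich in Malat1. With classes drawn and tested on separate random parts of the counts, Abcb1a turned to +0.72, which itself passed (adjusted p = 0.0495). That setting held 3 fibroblast-like classes, without arachnoid barrier-like cells and cluster F06, so the other side of the comparison differed.

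Arachnoid barrier-like cells, the cells that seal the arachnoid against the dura, had more Abcb1a, which encodes the efflux pump P-glycoprotein (chromosome 5, 8660077 to 8748575). It stood at 692 and 720 CPM against 268 and 296, a log2 fold change of +1.69 ± 0.16 (adjusted p = 3.6e-13). Pial and inner arachnoid fibroblast-like cells, in which Abcb1a was lower, formed part of that other side. The fold change therefore does not show how far arachnoid barrier-like cells exceeded dural border-like cells or cluster F06 alone. Igfbp3, which encodes an IGF-binding protein, was higher by 3.32 ± 0.40 (1.90 without R2), the collagen gene Col25a1 by 2.72 ± 0.16 and Tnxb, which encodes a tenascin, by 2.53 ± 0.24. The complement regulator gene Cd55 was higher by 2.36 ± 0.19, Stra6, which encodes a retinol transporter, by 2.21 ± 0.17, and Bmp4 by 1.48 ± 0.15. Igf2 was lower at −2.90 ± 0.25, Slc7a11 at −2.80 ± 0.31 and Thbs1, which encodes thrombospondin, at −3.05 ± 0.40. Slc30a10 had 0 counts in these cells and was at least 8.66-fold lower than in the other fibroblast-like cells pooled, against a floor of 3 counts over both libraries. That pool includes the pial cells, in which Slc30a10 was higher, so the bound need not hold against each other class alone.

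Collagen genes gave 6 higher and 1 lower of 19 in arachnoid barrier-like cells (8 and 4 adjusted over the list alone; list adjusted p = 0.00354; adjusted p = 0.120 with an estimated correlation). Dissociation-response genes gave 5 higher and 0 lower of 13 (8 and 1 over the list alone), with Jun at +0.87 ± 0.24 (list adjusted p = 0.00223; adjusted p = 0.402 with an estimated correlation). Tight junction genes gave 1 higher and 0 lower of 9, and their test did not pass (adjusted p = 0.603). The member that passed was Lsr, a gene of tricellular junctions, at +1.05 ± 0.22. The list does not hold the claudin gene Cldn11, a marker that led this class. In all, 984 of 8687 genes passed, 645 higher and 339 lower, and 440 passed with the Wald test of DESeq2. This class rested on 121 and 67 cells and fell under 50 cells in a library, or did not form, at the lower resolution, with the list genes kept in the clustering, with at least 1000 genes per cell, with at most 5% or 25% mitochondrial UMIs and with classes drawn on a random part of the counts.

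Dural border-like cells, at the border between dura and arachnoid, were marked by Gdf10, a gene of the BMP family, at 264 and 305 CPM against 56.2 and 52.4. Its log2 fold change was +2.65 ± 0.18 (adjusted p = 1.5e-19). Col25a1 was higher by 2.18 ± 0.15, the cadherin gene Cdh11 by 1.76 ± 0.15 and the multidrug transporter gene Abcc4 by 1.71 ± 0.17. Some genes that were higher in the inner arachnoid fibroblast-like class were lower here, with Kcnj13 at −3.16 ± 0.31, Slc6a20a at −2.88 ± 0.28 and Ptgfr at −2.83 ± 0.40. Lum was lower at −2.77 ± 0.48.

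ABC transporter genes gave 8 higher and 1 lower of 11 in dural border-like cells over all genes and over the list alone (list adjusted p = 3.7e-06; adjusted p = 0.117 with an estimated correlation). Collagen genes gave 11 higher and 4 lower of 19 (12 and 5 adjusted over the list alone; list adjusted p = 4.4e-05; adjusted p = 0.118 with an estimated correlation). Prostaglandin and lipid carrier genes gave 2 higher and 6 lower of 9 over all genes and over the list alone, with Enpp2 at −2.53 ± 0.25 (list adjusted p = 6.1e-06; adjusted p = 0.120 with an estimated correlation). Cytokine, chemokine and complement genes gave 1 higher and 4 lower of 9 (2 and 4 over the list alone), with the cytokine gene Il34 at −2.01 ± 0.27 (list adjusted p = 0.0440; adjusted p = 0.352 with an estimated correlation). In all, 3196 of 8687 genes passed, 1745 higher and 1451 lower, the count was 1945 without cluster F06, and with at least 1000 genes per cell it was 1252. Under that last filter the calls of Thbs1, at +2.48 ± 0.17 otherwise, and of Ebf1, at +2.15 ± 0.33 otherwise, were lost, with values of 0.27 and −0.17 against inner arachnoid cells and a redrawn cluster alone, so that the comparison group changed as well, and Ebf1 was 1.38 without R2.

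**Figure D4:**
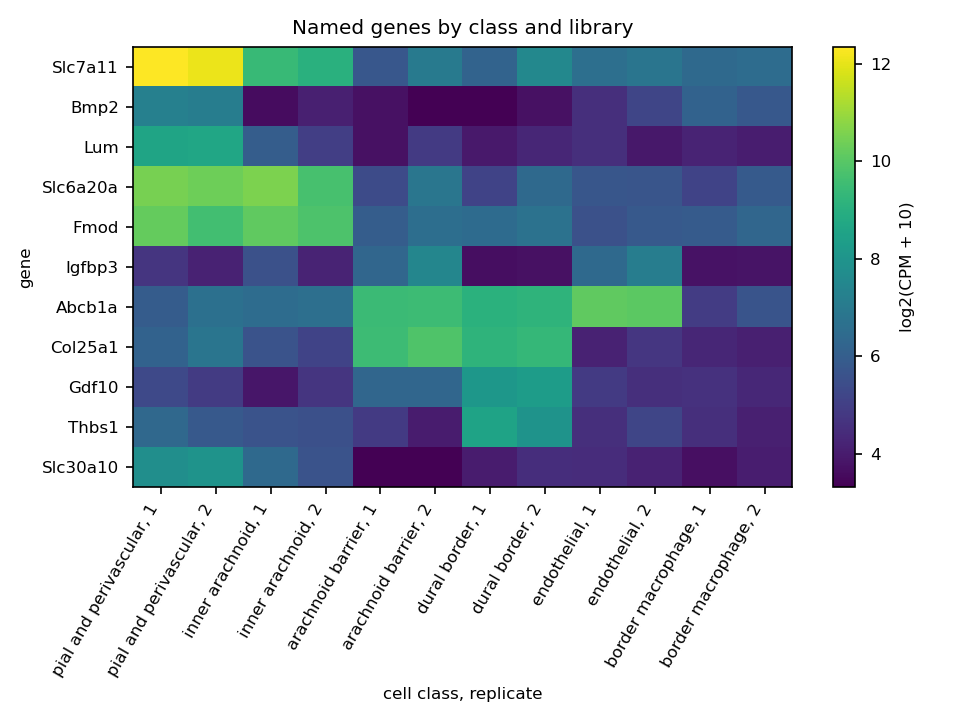
Level of 11 named genes (vertical axis) in each library of 6 cell classes (horizontal axis), as log2 of CPM plus 10 (colour). Slc7a11 was highest in pial cells, with 5196 and 4315 CPM, Abcb1a was higher in arachnoid barrier-like cells than in pial cells, and Gdf10 was highest in dural border-like cells, with 264 and 305.

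The next comparison set the arachnoid barrier-like cells against endothelial-like cells, since both form barriers with junctions and transporters. Arachnoid barrier-like cells had more Igfbp6 (2390 and 2614 CPM against 83.3 and 117, log2 fold change +4.44 ± 0.22), Gja1 (+3.6 ± 0.23), Cd55 (+4.41 ± 0.30) and Col25a1 (+5.83 ± 0.29). Organic ion and nutrient carriers gave 11 higher and 13 lower of 36 (12 and 13 over the list alone; adjusted p = 0.766) and ABC transporter genes 5 higher and 4 lower of 15 over all genes and over the list alone (adjusted p = 0.679), and neither test passed. Pooled over both libraries, 3 UMIs of the glucose transporter gene Slc2a1 in arachnoid barrier-like cells stood against 2616, a ratio of 310 (counting interval 106 to 1503). The organic anion carrier gene Slco1a4 had 3 UMIs against 2695, a ratio of 319 (109 to 1548), and Esam, which encodes an endothelial adhesion molecule, 1 UMI against 1216, a ratio of 432 (77.4 to 17069). Gja4 and Cxcl1 had 0 counts and were at least 11.1-fold and 10.3-fold lower, against a floor of 3 counts over both libraries.

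Tight junction genes gave 0 higher and 7 lower of 11 in arachnoid barrier-like cells over all genes and over the list alone, with Jam2 at −4.25 ± 0.37 and Ocln, which encodes occludin, at −3.88 ± 0.41 (list adjusted p = 1.8e-04; adjusted p = 0.162 with an estimated correlation). The list has 23 members, of which 11 were tested. It leaves out the claudin genes Cldn11 and Cldn5, which served as markers of arachnoid barrier-like and endothelial-like cells, so these counts do not cover them. Transcription factors of the meninges gave 19 higher and 4 lower of 25 over all genes and over the list alone, with Prrx2 at +4.70 ± 0.43 (list adjusted p = 2.1e-09; adjusted p = 0.0692 with an estimated correlation). Foxf1 had 0 counts and was at least 12.1-fold lower. Collagen genes gave 12 higher and 3 lower of 19 (13 and 3 adjusted over the list alone; list adjusted p = 3.6e-06; adjusted p = 0.0712 with an estimated correlation). BMP and WNT pathway genes gave 10 higher and 3 lower of 16 over all genes and over the list alone, with Bmp4 at +3.85 ± 0.24 (list adjusted p = 4.3e-06; adjusted p = 0.117 with an estimated correlation). Proteoglycan and matrix glycoprotein genes gave 11 higher and 4 lower of 22 over all genes and over the list alone, with Tnxb at +4.54 ± 0.39 (list adjusted p = 0.00569; adjusted p = 0.120 with an estimated correlation). Inorganic ion and water transport genes gave 9 higher and 6 lower of 22 (10 and 6 over the list alone; list adjusted p = 0.0237; adjusted p = 0.129 with an estimated correlation). That list's median, 0.44, and mean, −0.05, of the log2 fold changes had opposite signs.

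Dissociation-response genes gave 0 higher and 17 lower of 17 in this comparison over all genes and over the list alone, with Fos at −6.64 ± 0.32 (list adjusted p = 1.4e-14; adjusted p = 0.120 with an estimated correlation). Endothelial-like cells had 1399 and 1888 CPM of Fos, and 1 of their clusters was led by Atf3, Fos and Jun. In all, 3268 of 10564 genes passed, 1451 higher and 1817 lower. Pdgfra was higher by 1.88 ± 0.71 (adjusted p = 0.0284), on 5 and 6 UMIs against 5 and 2. That call was lost without the filter on low counts (1.82) and at the higher resolution (1.59), turned to −0.13 with equal UMI totals, and was 0.74 without R2.

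Cluster F06, the fibroblast-like cluster poor in Malat1, was compared in the same way with the 4 named fibroblast-like classes. Mgp, which encodes a matrix protein that inhibits calcification, was higher by 1.57 ± 0.14 (6799 and 8591 CPM against 3256 and 4209), and Six2 by 1.53 ± 0.23. Vegfa was lower at −2.74 ± 0.44, the multidrug transporter gene Abcc5 at −2.13 ± 0.29 and Zic4 at −1.58 ± 0.19. Of 34 organic ion and nutrient carriers 5 were higher and 18 lower over all genes and over the list alone, with Slc16a6 at −2.17 ± 0.28 (list adjusted p = 5.0e-04; adjusted p = 0.350 with an estimated correlation). In all, 3520 of 8687 genes passed, 1850 higher and 1670 lower, and 2040 passed with the Wald test of DESeq2.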

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

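The tests of lower depth, of endothelial-like and mural-like cells alone, of B cell RNA and of plasma cell RNA were chosen only after the result was seen, as were the settings with at least 1% Malat1 and at most 25% mitochondrial UMIs.

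Xist, the transcript of the inactive X chromosome, gave 2315 UMIs in all barcodes of R1 and 13 in R2, in data that no comparison used, while 4 Y-linked genes gave 2142 and 2051 UMIs. The labels name males and females and do not say how the sexes were spread over the libraries, and the few Xist UMIs leave little room for female cells in R2. R1 thus held female cells that R2 almost lacked, which argues against both libraries being loads of the same cell suspension. Barcodes with 10% to 25% mitochondrial UMIs, left out of the comparisons, were fibroblast-like in 53.4% of 2670 barcodes of R1 (51.5 to 55.3) and 64.5% of 2260 of R2 (62.5 to 66.4) against 46.95% and 51.1% of the kept cells.

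The large cluster F06 held little Malat1, a median of 0.103% and 0.0967% of UMIs, and Malat1 was itself among the variable genes used for clustering. Named fibroblast-like cells with UMI totals at or under the cluster's medians had medians of 0.285% and 0.159%: 3.99% and 0.519% in dural border-like, 3.86% and 2.04% in pial, 0.415% and 6.33% in arachnoid barrier-like (5 and 6 cells), but 0.141% and 0.0650% in inner arachnoid cells, which were 51 of 95 and 94 of 152. The first 3 classes go against lower depth as the cause, but it stays open, since the pooled shallow cells of R2 were within 2 times the cluster, the inner arachnoid cells of R2 below it, and Malat1 helped to sort these cells into classes. Loss of nuclear RNA is a candidate explanation: across genes, which are not independent replicates, the log2 ratio of the cluster to Malat1-rich named fibroblast-like cells correlated with that of Malat1-poor to Malat1-rich border macrophage-like cells (Pearson r = 0.497 over 7485 genes in R1 and 0.537 over 7441 in R2). Free RNA of other classes cannot be told apart from it, since the median log2 ratio over 19 macrophage, endothelial and erythroid markers was 1.01 in R1, past the bound of 1 set in advance for this explanation, and 0.588 in R2, short of it but above the bound of 0.5 against it, and no biological explanation was tested.

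All 17 dissociation-response genes were lower in fibroblast-like cells than in the mean of the other classes. Among barcodes with at least 1% Malat1 UMIs, where endothelial-like and border macrophage-like cells were the only other classes with enough cells, 15 of 17 were still lower. This met the bound set in advance exactly and argues against barcodes with little nuclear RNA as the whole cause. Against microglia-like cells alone 14 of 17 were lower, so endothelial-like and mural-like cells alone do not account for the difference. Against border macrophage-like cells 7 were lower and 2 higher. The digestion was the same for all classes of a library, and no biological explanation was tested.

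Inner arachnoid fibroblast-like cells held Cd79a, a gene of the B cell receptor (chromosome 7, 24897381 to 24902197), in 31 of 237 cells of R1 and 34 of 414 cells of R2. RNA of B cells was argued against as the main source of Cd79a, since these cells had 79 Cd79a and 0 Cd79b UMIs, an upper 95% bound of 4.56% Cd79b, against 37.6% (33.6 to 41.7) in B-like cells. These bounds pool UMIs over cells and libraries as if they were independent. Immunoglobulin genes were among the leading genes of 1 of their clusters, but RNA of plasma cells does not account for Cd79a either, since Igkc UMIs per Cd79a UMI were 1.76 and 0.220 against 468 and 617 in the unnamed cluster C19, which immunoglobulin genes lead. Transcripts read through from Rps19, which lies upstream on the same strand (24884371 to 24889806), were argued against by a ratio of Cd79a to Rps19 UMIs that was 42.4 and 16.1 times that of the other named fibroblast-like cells (38 and 41 Cd79a UMIs against 5 and 2). Other sources of these transcripts, such as an unannotated start, were not tested, nor was a biological explanation.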

How the results depend on the processing

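Added after seeing the data were at most 25% mitochondrial UMIs, removal of the top doublet scores, at least 1% Malat1 UMIs and leaving out cluster F06. Pdgfra, given below, is not part of these totals: of 2950 values of 224 named gene results over the tested alternatives, 2818 kept their direction and side of the threshold, 124 fell below it and 8 reversed. Without R1, 99 of the 224 lay further from the main value than the SD between libraries, and without R2 95 did. The main value came from the fitted model, and the single-library values from logs with a prior count. With a single estimator, neither library's value could lie further from their mean than that SD. These counts therefore do not measure the effect of losing a library. The classes compared also changed where clusters were redrawn or barcodes left out: with at most 5% mitochondrial UMIs and with count splitting 3 fibroblast-like classes were left, dural border-like, inner arachnoid and pial, and with at least 1000 genes a redrawn cluster took the place of the pial class. Where values changed, the cause was not tested, except that equal UMI totals leave fewer counts and genes. Single-library values come from logs with a prior count of 2 and have no test, since 1 library leaves no residual. The arachnoid barrier-like class gave no tested values at the lower resolution, with list genes kept, at least 1000 genes, at most 5% or 25% mitochondrial UMIs and count splitting. Cluster F06 has values only where the clusters were not redrawn.

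Mean shares of all fibroblast-like cells were 40.9% with at least 1000 genes, 34.5% with at most 5% and 52.6% with at most 25% mitochondrial UMIs. In that order and then with at least 1% Malat1, arachnoid barrier-like shares were 1.09%, 1.66%, 0.912% and 5.81%, and dural border-like shares 19.0%, 20.9%, 21.4% and 25.9%. Inner arachnoid shares were 6.39% with at least 1000 genes, 6.05% with at most 25% mitochondrial UMIs and 5.65% with at least 1% Malat1, and pial shares 10.2% with at least 1% Malat1. The lower resolution gave 7.02% pial and 7.37% dural border-like cells, and list genes kept in the clustering 1.25% arachnoid barrier-like cells.

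Genes past the threshold with equal UMI totals were 1621 (fibroblast-like against other classes), 964 (arachnoid barrier-like against endothelial-like), 618 (arachnoid barrier-like), 1236 (dural border-like), 1859 (cluster F06), 829 (inner arachnoid) and 1384 (pial). The Wald test of DESeq2 gave 440, 1328, 2040, 853 and 1448 for the last 5 of these. Count splitting gave 3257 for fibroblast-like against other classes, 1440 for dural border-like and 1559 for pial cells. Dural border-like counts were 1945 without cluster F06, 1464 and 1451 at the lower and higher resolution, 1252 with at least 1000 genes, 1505 with at most 5% mitochondrial UMIs and 1433 with at least 1% Malat1. Inner arachnoid counts were 2804 at the lower resolution, 1052 with list genes kept, 735 with at most 5% mitochondrial UMIs and 1042 with at least 1% Malat1. Pial counts were 1513 without cluster F06, 750 and 3895 with at most 5% and 25% mitochondrial UMIs, and 1106 with at least 1% Malat1.

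Pdgfra in arachnoid barrier-like against endothelial-like cells was 1.82 without the count filter, 1.59 at the higher resolution and −0.13 with equal UMI totals. Against the other fibroblast-like classes, that of arachnoid barrier-like cells passed at −1.76 without cluster F06, −1.28 without doublet removal, −1.40 without the top doublet scores and −1.67 with at least 1% Malat1. That of dural border-like cells was −0.66 with equal UMI totals, and that of inner arachnoid cells 0.15 with at most 5% mitochondrial UMIs and 0.29 with count splitting. Leaving out each library gave 2.62 to 3.25 for fibroblast-like against other classes, 0.74 to 2.34 against endothelial-like cells, −1.56 to −0.47 for arachnoid barrier-like cells, −1.46 to −1.16 for dural border-like cells, −1.92 to −1.46 for cluster F06, 1.07 to 1.35 for inner arachnoid and 2.47 to 3.14 for pial cells. At 2000 UMIs per cell a Pdgfra UMI was seen in 34.1% of pial, 4.54% of arachnoid barrier-like and 4.77% of dural border-like cells. With count splitting, ABC transporters in fibroblast-like cells (adjusted p = 0.0820), carriers in inner arachnoid cells (0.0971) and the dissociation response in pial cells (0.234) no longer passed. Lists that passed only there were retinoid pathway (0.0102), cytokines (0.0446) and prostaglandin and lipid carriers (0.0185) in fibroblast-like cells, basement membrane (0.00891) and inorganic ion transport (0.0117) in inner arachnoid cells, and carriers, lower, in dural border-like cells (6.2e-06). In each of the 7 comparisons 0 lists passed camera with the estimated correlation, while 27 of 105 tests had an unadjusted p below 0.05.

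Reversed genes besides Pdgfra were Abcc4 in fibroblast-like cells (−0.35) and Jun in pial cells (0.30) with at most 5% mitochondrial UMIs, Hspg2 in arachnoid barrier-like against endothelial-like cells with equal UMI totals (0.030), Ebf1 with at least 1000 genes (−0.17) and Hspb1 at the lower resolution (0.042) in dural border-like cells, and Smoc2 (0.089), Abcb1a (0.72, the only one past the threshold, adjusted p = 0.0495) and Jun (0.31) in inner arachnoid cells with count splitting.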

Other observations

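Immune cells outside the named comparisons made up small shares of the kept cells. T or NK-like cells, led by Ccl5 and Nkg7, were 1.11% of R1 and 1.75% of R2, neutrophil-like cells, led by S100a8 and S100a9, 0.335% and 0.329%, and B-like cells, led by Cd79a, 0.503% and 0.329%. Within endothelial-like cells 1 cluster was led by Slco1a4 and Cldn5, genes of brain capillaries, and another by Eln and Bmx, genes of arteries. Within dural border-like cells cluster F00 (327 cells) had the antigen presentation genes Cd74, H2-Ab1 and H2-Eb1 among its leading genes, and 0 dural border markers among the first 10.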
